A study of Mus musculus with 24 samples.

How the data were processed

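Messenger RNA was measured in single mouse oocytes. Per the labels' protocols, the day of ovulation was found by vaginal lavage, the complexes were taken from the oviduct, hyaluronidase stripped the cumulus, acid Tyrode's solution dissolved the zona, and each oocyte was lysed on its own. Complementary DNA was amplified with the SMART-Seq v4 kit and libraries were made with ThruPLEX, per the labels' protocols. Neither source states that strand was kept, so antisense and overlapping genes could share reads. The labels list 24 samples: 22 oocytes from 8 females, a water-only library and a kit control RNA. The table has 22 columns of values, 21 for oocytes and 1 for the control RNA. Oocyte A of the transgenic female of lane 1 and the water-only library were not analysed here, so a planned background from water cannot be given.

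The submitters' processing notes name Trim Galore, FastQC and HISAT2, and the builds GRCm39 and mm39, with no versions. The counting tool, the annotation release and the treatment of reads with several matches are not given in the sources used here. Gene coordinates in the table were those of GRCm38: of 25035 gene IDs matched to GENCODE M21, 99.8% overlapped the M21 gene and 69.0% had the same start. All coordinates here are the table's own, read as GRCm38. The deposited values are log2 values that the authors made per library. The deposited table is described as RPKM, but its values are log2 RPM, the reads of a gene per 1000000 reads of the library, with no division by gene length. In each column a gene without reads holds the value of 0.9 reads, and whole reads were recovered from the distance to that minimum. Of 256342 values above 0 and below 2000 reads, 100% lay within 0.02 of a whole read, and 99.84% of all values above 0 did. The 25965 entries carry 25899 distinct symbols; 66 share a symbol with an earlier entry, and 25 symbols had been altered to dates. Symbols are given as in the table, some of them older names (Ccrn4l is Noct in M21).

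RPM was computed from the recovered reads and the library total implied by each column, with genes without reads set to 0. Library totals of the oocytes were 20400000 to 33300000 reads (median 22500000), of which 91.1% to 94.8% lay in listed genes, and 3 reads corresponded to 0.0900 to 0.147 RPM. No 2 libraries were the same: Pearson's r across tested genes ran from 0.907 to 0.973 between oocytes, with a median of 0.957 within a female and 0.950 between females.

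The following choices were made before the data were examined unless stated. Values were log2(RPM + 1), a scale that understates the change of low genes. Genes with a mean of at least 1 RPM over the oocytes were tested (10987). The oocytes of a female were averaged, and the 4 transgenic and 4 wild-type females were compared with limma 3.58.1 (lmFit, eBayes with trend) in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The plan had named RPKM for the pseudocount and the filter; RPM took its place. Gene lists were 22, fixed beforehand; those with at least 5 tested members (20) were tested with camera (preset correlation 0.01), camera with an estimated correlation, and fry. Of 530 genes listed by name 2 matched no entry; the ribosomal and proteasome lists were filled by symbol pattern. Single values of females were compared with exact permutation tests over 70 arrangements, two-sided, which cannot go below 0.029, and within lanes with sign flips over 4 pairs, which cannot go below 0.125. Count models were not used, since the deposited unit is log2; limma voom on recovered reads was added after the data were seen.

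The lane pairs the females, since the labels give each lane 1 female of each genotype. Deviations of lane mates from their group means correlated across genes at -0.04, 0.084, 0.34 and 0.32 in lanes 1 to 4, against a median of -0.055 for other pairs.

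The named genes were fixed by rule: Amh, Amhr2 and Thy1; where fewer than 10 genes passed in a direction, those that passed and the smallest p up to 8 per direction with 1 sign in all 4 lanes, marked as not passing; and up to 3 members of each list with the smallest p. Symbols of the form Gm plus digits, Rik or -ps were left out. The most abundant transcripts and further cell type markers are also named outside this rule. Other genes named outside it are said to be so.

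The tests were run on simulated data drawn from the genes' own means, library totals and spread within and between females, 5 times with 100 changed genes of each size, all with a mean of at least 5 RPM. No lane effect was simulated. With the female means, 94.8% of genes changed by a log2 of 2 and 52.6% of genes changed by a log2 of 1 were recovered over 10961 genes, with 8 false calls on average. With the lane as a block it was 94.2% and 38.2% with 5.2 false calls, and with single oocytes, the female as random effect and the lane as block 98.4% and 75.2% with 75.6 false calls. Of 15 simulated lists of 30 genes shifted by a log2 of -0.4, camera called 15, and of 85 unshifted lists it called 0 over 10987 genes; the genes of these lists varied independently, unlike those of real lists. Alternatives were the lane as a block, oocytes in place of female means, weights, pseudocount, filters, 2 other scalings, eBayes settings, 1 female left out at a time and lanes 1 to 3. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 read the table and drew the plots.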

Results

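Anti-Müllerian hormone (AMH) is made by the granulosa cells of growing follicles and restrains follicle recruitment. The study asked whether raised AMH alters the transcripts of the oocyte itself. Single oocytes were taken after natural ovulation from wild-type mice and from mice carrying a Thy1.2-AMH transgene, in which a Thy1.2 promoter drives AMH. Each genotype had 4 females with 2 or 3 oocytes each, and each of the 4 sequencing lanes held 1 female of each genotype. Values of 11 wild-type and 10 transgenic oocytes and of 1 kit control RNA were analysed. A further transgenic oocyte of lane 1 and the water-only library are not analysed here. The female was the replicate, so n = 4 in each group. Library totals of the oocytes ran from 20400000 to 33300000 reads, and 3 reads stood for 0.0900 to 0.147 RPM, where RPM is the reads of a gene per 1000000 reads of the library.

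Known egg transcripts were the most abundant. Across the 21 oocytes these were Zbed3 at 16800 ± 3092 RPM (SD over 21 oocytes), Tcl1 at 10170 ± 1141 RPM, and Bcl2l10 at 10093 ± 1653 RPM. The linker histone H1foo stood at 8316 ± 1500 RPM, the decay adaptor Btg4 at 7218 ± 1327 RPM and the secreted growth factor Gdf9 at 5142 ± 1676 RPM. The control RNA held 5.08 RPM of Gdf9 and 6070 RPM of the myelin gene Mbp.

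Amh itself (chromosome 10, 80805248 to 80807648, GRCm38) was examined first, as a check of the genotype labels. It had 0 reads in the 10 transgenic oocytes, which allows up to 0.0125 RPM over the group (3 reads), and 1 read over the 11 wild-type oocytes. Its receptor gene Amhr2 (chromosome 15, 102445367 to 102454630) had 0 reads in the transgenic oocytes and 4 reads in 1 wild-type oocyte. Thy1 (chromosome 9, 44043384 to 44048579), the source of the transgene's promoter, had 7 reads in 1 transgenic oocyte and 0 reads in the wild-type oocytes, against 713 reads in the control RNA. Mean log2(RPM + 1) of Thy1 differed by 0.034 between the genotypes (exact permutation test of the females, two-sided, p = 1; n = 4 and 4). Whether the transgene holds the mouse Amh sequence is not given in the sources used here, so these genes could not check the genotype labels. Floors and counts here cover counting error only, since amplified reads are not independent molecules.

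The comparison of the genotypes asked which transcripts of the oocyte differ when AMH is raised, and no gene passed the threshold. Ccrn4l, which had the smallest p and encodes nocturnin (chromosome 3, 51224447 to 51251644), stood at 743 ± 170 RPM in transgenic and 392 ± 41.7 RPM in wild-type oocytes (SD, n = 4 females), a log2 difference of 0.90 ± 0.17 (SE). Eif1b, a translation initiation factor (chromosome 9, 120492606 to 120495327), stood at 193 ± 36.2 RPM in transgenic and 338 ± 96.8 RPM in wild-type oocytes, a log2 difference of -0.81 ± 0.20. Birc5, the chromosomal passenger protein survivin (chromosome 11, 117849251 to 117855743), stood at 196 ± 55.8 and 345 ± 87.6 RPM, a log2 difference of -0.82 ± 0.22. Each of these 3 differences had 1 sign in all 4 lanes, which the naming rule required of Ccrn4l and Eif1b. Of all tested genes 18.3% had 1 sign in all 4 lanes, against 12.5% by chance. Of 10987 genes tested with limma on female means, 0 were higher and 0 lower at a Benjamini-Hochberg adjusted p under 0.05. The smallest adjusted p was 0.724, and 748 genes had an unadjusted p under 0.05 (305 higher and 443 lower in the transgenic oocytes). In simulations of this comparison over 10961 genes, the same test recovered 94.8% of genes changed by a log2 of 2 and 52.6% of those changed by a log2 of 1, all with a mean of at least 5 RPM. Each simulation held 100 changed genes of each size. Where fewer genes change, the adjusted threshold is stricter, and recovery in that case was not measured. With the lane as a block limma also called 0 genes (smallest adjusted p 0.447, 1028 genes at an unadjusted p under 0.05).

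**Figure D1:**
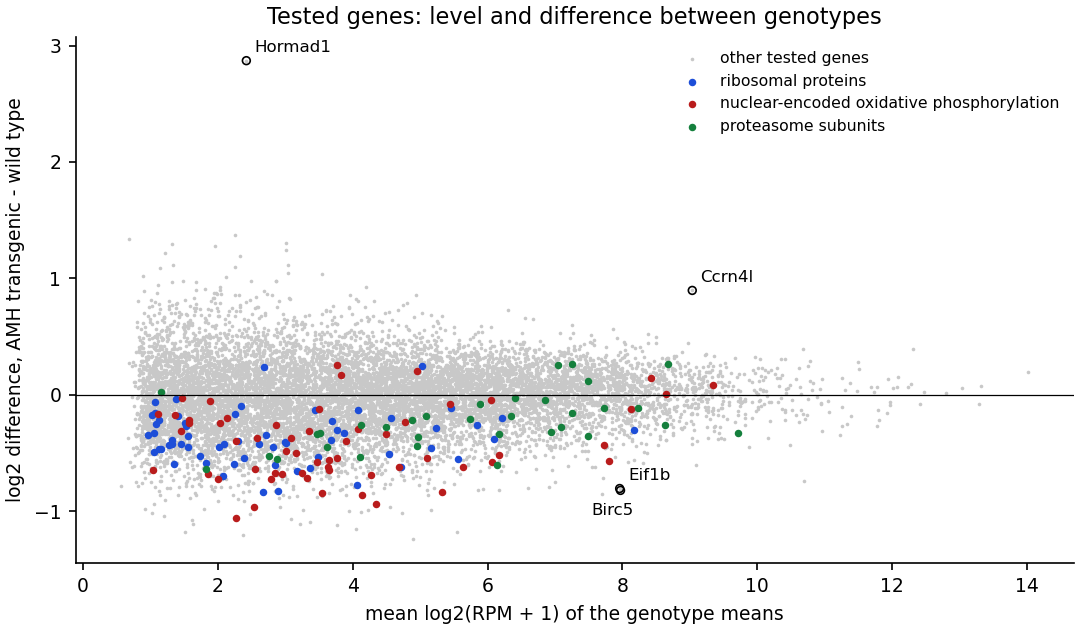
Log2 difference between AMH transgenic and wild-type oocytes (vertical axis, positive where the transgenic mean is higher) against mean log2(RPM + 1) (horizontal axis) for the 10987 tested genes, 1 point per gene. Most ribosomal protein (blue), oxidative phosphorylation (red) and proteasome (green) genes lie below 0, and Hormad1 lies at 2.87.

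Among genes higher in the transgenic oocytes, the fixed rule named 7 beside Ccrn4l. They were Acad9 (an assembly factor of respiratory complex I, 19.6 ± 1.56 against 11.3 ± 0.98 RPM), Tlr8 (an endosomal RNA sensor, 3.31 ± 1.43 against 0.607 ± 0.356 RPM), Wdr19 (intraflagellar transport, 21.2 ± 3.95 against 11.1 ± 0.889 RPM), Cnga4 (a cyclic nucleotide-gated channel subunit), Plac1, Grn (progranulin, 131 ± 20.8 against 83.6 ± 12.1 RPM) and Kcng3 (a potassium channel subunit). Their log2 differences ran from 0.65 for Grn to 1.30 for Plac1. Among genes lower in the transgenic oocytes, the rule named Fahd2a (1.06 ± 0.19 against 3.71 ± 1.81 RPM), Nudt1 (a hydrolase of oxidised nucleotides, 4.63 ± 0.93 against 9.54 ± 0.71 RPM), Mpnd, Eif1b, Ifitm6 (95.1 ± 25.9 against 160 ± 10.5 RPM), Pfdn5 (a prefoldin subunit, 77.8 ± 25.5 against 129 ± 6.26 RPM), Ndufa5 (a subunit of complex I) and Cd209g. Their log2 differences ran from -1.18 for Fahd2a to -0.78 for Cd209g. The limma adjusted p of each of these 16 genes was 0.724.

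Hormad1, a protein of the meiotic chromosome axis (chromosome 3, 95559677 to 95587671), had the largest difference among the named genes, 2.87 ± 0.81 on the log2 scale, and was uneven among the transgenic females. It stood between 10.9 and 67.9 RPM in the 8 transgenic oocytes of lanes 2 to 4, between 0.145 and 2.43 RPM in the 11 wild-type oocytes, and at 0.0900 and 0.994 RPM in the 2 transgenic oocytes of lane 1. Its limma adjusted p was 0.724 over all females. Without the transgenic female of lane 1 it was 0.00182 with a log2 difference of 3.97, and Hormad1 was then the 1 gene past the threshold; over 28 alternatives its adjusted p ran from 0.00182 to 0.973.

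**Figure D2:**
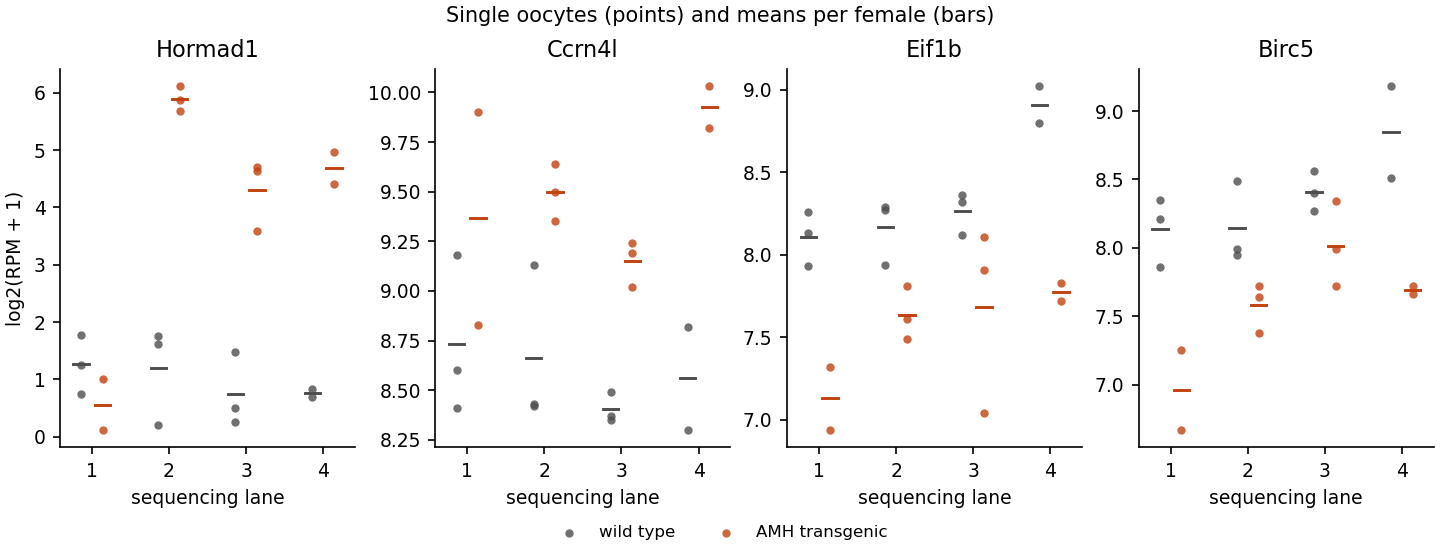
Log2(RPM + 1) of Hormad1, Ccrn4l, Eif1b and Birc5 in single oocytes (points) and the mean of each female (bars) by sequencing lane, wild type in grey and AMH transgenic in orange; the vertical axes of Ccrn4l, Eif1b and Birc5 do not start at 0. The 3 transgenic females of lanes 2 to 4 have Hormad1 means of 5.89, 4.31 and 4.68, and the transgenic female of lane 1 has 0.56.

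When the 21 oocytes entered the fit singly, with the female as a random effect and the lane as a block, limma called 12 genes, 4 higher and 8 lower in the transgenic oocytes. Ccrn4l (adjusted p = 0.0085), Hormad1 (0.0085), Eif1b (0.0085), Birc5 (0.0148) and Ifitm6 (0.0289) were among them. In simulations over 10961 genes this fit made 75.6 false calls on average, against 8 with the test on female means. These simulations held 100 changed genes of each size and no lane effect, so 75.6 is not an estimate for the 12 genes. With genotype swapped within lanes in the real data, the same fit called at most 5 genes. Oocytes taken as independent gave 2 genes, voom on reads summed per female 0, and voom on oocytes with the lane 15, 11 of them among the 12.

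Transcripts of ribosomal proteins, of nuclear-encoded oxidative phosphorylation and of the proteasome were lower in the transgenic oocytes as groups by camera with a preset correlation. With an estimated correlation the adjusted p were 0.42, 0.41 and 0.41, so none of the 3 calls held. Of 62 tested ribosomal protein genes 60 were lower, 13 of them at an unadjusted p under 0.05, with a median log2 difference of -0.40. Rps3a stood at 4.81 ± 0.83 against 9.43 ± 2.16 RPM (transgenic against wild type), Rpl14 at 6.54 ± 1.48 against 10.6 ± 1.35 RPM and Rpl23 at 2.56 ± 1.06 against 4.51 ± 0.92 RPM. How reads shared with pseudogenes were counted is not given, so these values may not hold all reads of a gene. Low values were not confined to this list. Gapdh, named outside the rule, stood at 3.68 RPM in the control RNA, against 311 RPM of Actb, and at most at 0.6 RPM in the oocytes. Of 58 nuclear-encoded genes of oxidative phosphorylation 52 were lower, 17 of them at an unadjusted p under 0.05, with a median of -0.46. Ndufa5 stood at 2.55 ± 1.16 against 6.53 ± 2.18 RPM, Ndufa6 at 12.7 ± 4.39 against 23.6 ± 4.02 RPM, and Cox6c, a subunit of cytochrome c oxidase, at 30.8 ± 8.21 against 57.0 ± 21.0 RPM. Of 33 proteasome subunit genes 28 were lower, 3 of them at an unadjusted p under 0.05, with a median of -0.26. Psmd10 stood at 4.77 ± 0.76 against 7.15 ± 0.20 RPM and Psma3 at 14.0 ± 4.05 against 19.9 ± 2.10 RPM. In none of the 3 lists did a gene pass over all genes tested or adjusted over the list alone, where the smallest limma adjusted p were 0.22, 0.10 and 0.38.

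The mean over each of these lists was lower in the transgenic female than in the wild-type female of the same lane in all 4 lanes. The mean log2(RPM + 1) over the ribosomal proteins was 2.66 ± 0.24 in transgenic and 3.03 ± 0.11 in wild-type females (SD, n = 4). Over oxidative phosphorylation it was 3.66 ± 0.24 against 4.08 ± 0.15, and over the proteasome 5.61 ± 0.12 against 5.84 ± 0.10. With camera and a preset correlation of 0.01 the adjusted p over 20 lists was 1.8e-11 for the ribosomal proteins, 7e-11 for oxidative phosphorylation and 0.0017 for the proteasome. Fry gave an adjusted p of 0.16 for each. An exact permutation test of the females on each list mean, two-sided and added after the data were seen, gave p = 0.029 for each, the smallest it can give with 4 and 4, and an adjusted p of 0.14 over the 20 lists. The summed level of ribosomal protein transcripts was 922 ± 192 against 1174 ± 120 RPM (exact permutation p = 0.0571, 0.257 after adjustment over the 9 single-value comparisons). A library property, the share of reads in listed genes, also differed, with a median of 93.34% in transgenic and 92.24% in wild-type oocytes. Across the oocytes the summed ribosomal level mostly fell as this share rose. The part of the share in the list differences was not tested. The antioxidant list, which camera did not call (adjusted p = 0.17), had the same exact permutation p of 0.029, a lower transgenic mean in all 4 lanes and a fry adjusted p of 0.16. Without the transgenic female of lane 1 the medians were -0.27, -0.30 and -0.14, and without the wild-type female of lane 3 or of lane 4 that of the proteasome was -0.16.

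**Figure D3:**
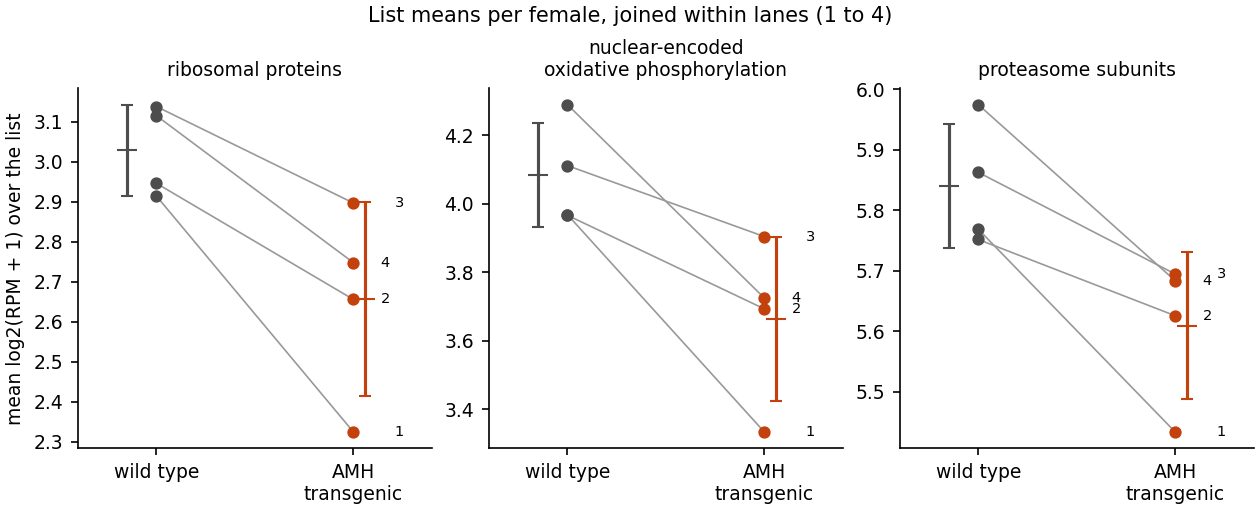
Mean log2(RPM + 1) over the tested members of 3 gene lists (vertical axes, which do not start at 0) for each female, wild type in grey and AMH transgenic in orange, with the females of a lane joined by a line and the lane number at the right. Bars beside the points give the mean and SD of the 4 females; in each list the line falls in all 4 lanes.

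Lists of the oocyte's own programme did not pass. Of 27 tested maternal-effect genes 11 were higher and 16 lower, with Zar1l at 30.2 ± 6.45 against 40.4 ± 7.59 RPM (transgenic against wild type) and Pou5f1 at 113 ± 30.4 against 147 ± 40.3 RPM. Of 19 oocyte-secreted factors and zona genes 7 were higher and 12 lower, with Gdf9 at 6034 ± 1130 against 4672 ± 1317 RPM and Plac1l, the egg protein Oosp2, at 151 ± 38.1 against 211 ± 34.5 RPM. Of 30 genes of maternal mRNA storage and decay 18 were higher and 12 lower, with the RNA-binding Ybx2 at 12.6 ± 2.07 against 17.7 ± 2.24 RPM and the m6A reader Ythdf2 at 87.1 ± 23.8 against 64.8 ± 9.03 RPM. Of 34 genes of the meiotic cell cycle 16 were higher and 18 lower, with the kinetochore gene Ndc80 at 184 ± 38.5 against 137 ± 12.5 RPM beside Birc5. Of 16 cohesin and recombination genes 11 were higher, led by Hormad1, and of 17 egg activation genes 10 were higher. The sperm-fusion tetraspanin Cd9 stood at 12.5 ± 1.36 against 32.7 ± 27.6 RPM, a log2 difference of -0.99 that was -0.54 without the wild-type female of lane 4. The camera adjusted p of these 6 lists were 0.92, 0.92, 0.91, 0.91, 0.64 and 0.92, and 0 of their members passed over all genes tested or adjusted over the list alone (limma).

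Signalling, stress and energy lists did not pass either. Of 18 tested genes of AMH, BMP and activin signalling 10 were higher and 8 lower (camera adjusted p = 0.64), with Smurf1 at 40.3 ± 6.92 against 32.7 ± 6.76 RPM and the activin receptor Acvr2a at 7.66 ± 2.13 against 5.50 ± 1.21 RPM. Of 22 genes of PI3K, FOXO3 and mTOR signalling 13 were lower (0.92), with Akt1 at 214 ± 116 against 134 ± 35.3 RPM and Pik3cb at 13.8 ± 2.63 against 19.2 ± 3.52 RPM. Of 25 antioxidant genes 18 were lower (0.17), with Txn1 at 22.9 ± 6.27 against 33.7 ± 2.28 RPM and Prdx2 at 466 ± 112 against 616 ± 98.1 RPM, while glutathione reductase Gsr stood at 5.29 ± 2.73 against 2.77 ± 1.96 RPM. Of 28 genes of DNA damage and apoptosis 16 were lower (0.92), with the germline guardian Trp63 at 36.4 ± 5.76 against 25.8 ± 5.42 RPM and Mdm2 at 301 ± 61.0 against 234 ± 14.9 RPM. Of 35 chromatin regulators 20 were lower (0.92), with the histone demethylases Kdm1b at 181 ± 39.5 against 134 ± 17.6 RPM and Kdm5b at 9.16 ± 2.24 against 11.9 ± 1.96 RPM. Of 22 heat shock and unfolded protein genes 12 were higher (0.92), with Atf4 at 42.1 ± 6.54 against 56.2 ± 7.46 RPM. Of 20 glycolytic genes 12 were lower (0.92), with Pfkl at 21.0 ± 4.10 against 13.5 ± 3.36 RPM and Ldhb at 1317 ± 248 against 2459 ± 1631 RPM, a log2 difference of -0.74 that was -0.36 without the wild-type female of lane 4. Of 12 mitochondrially encoded genes 9 were lower (0.85), with mt-Nd6 at 192 ± 89.4 against 233 ± 59.9 RPM and mt-Co1 at 761 ± 291 against 780 ± 83.3 RPM. The mitochondrial mean was lower in lane 1 alone (-0.72, 0.22, 0.03 and 0.024 in lanes 1 to 4), and without the transgenic female of lane 1 the log2 difference of mt-Co1 was 0.0471. In these 8 lists 0 members passed over all genes tested or adjusted over the list alone (limma). The mean and median had opposite signs in the egg activation, glycolysis, heat shock and mRNA storage lists, and the camera direction was higher against a lower median in the damage, glycolysis and meiotic cell cycle lists.

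Whether the number of genes detected differed could not be decided with 4 females in each group. Transgenic females averaged 10753 ± 38.9 and wild-type females 10841 ± 36.4 genes at an RPM of at least 1 (SD, n = 4), a difference of -88.2. The exact permutation test, two-sided, gave p = 0.029, the smallest it can give, and 0.257 after adjustment over 9 single-value comparisons. After this adjustment a p of 0.029 stays above 0.05 unless most of the 9 comparisons reach it. The transgenic female was lower in all 4 lanes (exact sign flips of the pairs, p = 0.125, the smallest they can give). At an RPM of at least 10 the difference was -107 and at 0.1 it was 109 (exact permutation p = 0.0857 and 0.657). The median SD of a gene between oocytes of 1 female was 0.314 ± 0.077 in transgenic and 0.306 ± 0.056 in wild-type females on the log2 scale (exact permutation p = 0.886). The consensus correlation of oocytes of 1 female was 0.157 with genotype in the model and 0.0495 with the lane added.

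Markers of the cells around the egg were low apart from Cyp19a1, Kitl and Nr5a2, which were at or above 1 RPM in all 21 oocytes and were set aside after their levels were seen. Of the 30 other cumulus and granulosa markers, the summed level was 3.63 ± 1.01 RPM in transgenic and 7.89 ± 8.63 RPM in wild-type females (exact permutation p = 0.457, n = 4 and 4), with 20.5 RPM in the wild-type female of lane 2, raised by 1 oocyte at 54.3 RPM. Over the full list the sum was 94.0 ± 7.94 against 87.8 ± 7.53 RPM, higher in the transgenic female in all 4 lanes (exact permutation p = 0.314, n = 4 and 4). Cyp19a1, the aromatase gene, stood at a median of 64.5 RPM. The haemoglobin genes Hba-a1 and Hbb-b1 had 0 RPM in the oocytes, against 32.9 and 74.0 RPM in the control RNA. Of the same blood and immune list, Csf1r stood at a median of 10.6 RPM and Laptm5 at 6.68 RPM, both at or above 1 RPM in all 21 oocytes. Cd68 stood at a median of 2.65 RPM, at or above 1 RPM in 18 of 21. The marker lists of neurons and glia (6 tested genes, camera adjusted p = 0.92), oviduct epithelium (5 genes, 0.85) and sperm and early embryo (5 genes, all lower, 0.17) did not pass, with 0 members past the threshold over all genes or adjusted over the list alone. The mean of the sperm and early embryo list was lower in the transgenic female in all 4 lanes (exact permutation p = 0.171). The blood and the cumulus lists, with 3 and 4 tested genes, were too short to test. The brain-like control RNA had 14682 genes at an RPM of at least 1, against 10560 to 11027 in the oocytes.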

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

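Among the tests here, the splits of the 8 females and the sets matched on length and GC content were chosen after the result was seen, and the 3 cumulus markers left out of a sum after their levels were seen. Of 168 groups of 4 females tested for a female far from the other 3, 11 stood out, where chance gives about 8.4. The gap to the nearest female is given as a share of the group's range.

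Of these, 3 involved the wild-type female of lane 4: Ldhb (0.938; mean log2 12.2 against 10.6 to 10.7 in the others), Tcstv1 (0.922; 6.82 against 5.18 to 5.31) and Rps3a (0.962; 2.80 against 3.47 to 3.49). The transgenic female of lane 2 had low means over AMH, BMP and activin signalling (0.844; 4.58 against 4.81 to 4.86) and over DNA damage and apoptosis (0.866; 5.18 against 5.27 to 5.29). The transgenic female of lane 1 was low in Ifitm6 (0.889; 5.84 against 6.69 to 6.80) and high in Ythdf2 (0.830; 6.94 against 6.19 to 6.32). The wild-type female of lane 2 was high in Tlr8 (0.906; 0.958 against 0.465 to 0.511). The wild-type female of lane 3 was low in Kcng3 (0.879; 0.0833 against 0.446 to 0.496) and high in mt-Co1 (0.839; 9.80 against 9.47 to 9.52) and Dnaja1 (0.869; 7.58 against 7.26 to 7.31).

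With 0 genes past the threshold in the real split, 35 of the 35 splits of the 8 females into 4 and 4 had to give as many, so the count says nothing about chance; the highest of the others gave 9. At an unadjusted p under 0.05 the real split gave 748 genes and 5 of the 35 gave as many, with 1940 the highest of the others, which points to some structure among the females; the 4 larger splits part 0 or 2 of the lanes. Among the 8 splits that part all 4 lanes, which are too few for a share under 0.05, the real one gave 748 and the highest other 599. The 12 genes called from single oocytes with the lane as a block exceeded the other swaps of genotype within lanes, of which the highest gave 5; 1 of 8 gave as many, and 8 swaps are too few for a share under 0.05. For the count of 3 lists called with a preset correlation, chance cannot be excluded either, since 17 of the 35 splits called as many, 3 of them among the 8 that part all 4 lanes, and the highest of the others called 5.

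The lower level of ribosomal protein, oxidative phosphorylation and proteasome transcripts is the pattern to follow up. Chance cannot be excluded: with the 3 lists of smallest camera p picked anew in each split, 3 of the 35 splits gave a difference as large (0.359 in the real split, 0.375 in the highest other; 1 of 35 with these 3 lists kept, highest other 0.335). The 2 larger splits part 2 lanes, and among the 8 that part all 4, too few for a share under 0.05, the highest other gave 0.253. The exact permutation p adjusted over the 20 lists was 0.143. It could not fall under 0.05 unless most lists reached the smallest p, so it cannot decide. The log2 difference rose with transcript length across 10886 genes (Spearman rho 0.2). Random sets matched on length, GC content and level had a median of -0.069, against -0.354 for the lists, and 0% of 10000 sets were as low. That share cannot exclude length and GC content, since the lists were picked on these data and their genes vary together. With each oocyte's length and GC trend removed the median over the 3 lists was -0.28, so the trend as fitted accounted for part of the pooled difference. The ribosomal median went from -0.40 to -0.27 (exact permutation p = 0.0571). That of oxidative phosphorylation went from -0.46 to -0.38, and that of the proteasome stayed at -0.26. The 1 library that stands apart, oocyte C of the lane 1 transgenic female, is argued against as the whole cause, since without it the median was -0.34. Genotype and differences in egg age after ovulation or in poly(A) tails remain open and untested, as do reads shared with pseudogenes. A property of the library also remains open and untested. The oocyte with the largest share of reads in listed genes (94.81%) had the lowest ribosomal sum (617 RPM), and that with the smallest (91.13%) the highest (1472 RPM). The transgenic oocytes of lane 3 had 758, 1144 and 1472 RPM at 93.63%, 92.59% and 91.13%. Across the 21 oocytes the sum mostly fell as the share rose. In both females of lane 4, where shares were close, the oocyte with the larger share had the larger sum. At 93.33% oocyte A of the lane 2 transgenic female had 928 RPM and oocyte C of the lane 2 wild-type female 957 RPM. At 93.63% transgenic oocyte A of lane 3 had 758 RPM, and at 93.59% wild-type oocyte C of lane 1 had 933 RPM. How much of the genotype difference goes with the share was not tested.

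Hormad1 at 10.9 to 67.9 RPM in 3 of the 4 transgenic females, and at most 2.43 RPM elsewhere, is the second pattern, which Gm9000, a processed pseudogene on chromosome 13 (108670580 to 108671440) named Rps3a3 in M21 and chosen after its values were seen, shared with 0.96 to 4.94 RPM in those 8 oocytes and at most 0.0489 RPM in the other 13. RNA from cumulus cells is argued against by the cumulus markers without Cyp19a1, Kitl and Nr5a2. Of the other 5 females, 3 had a higher sum than the lowest of these 3, and 4 of the 5 over the full list. That rule was easily met, since 1 such female was enough. The wild-type females of lanes 1 and 2 had sums of 6.27 and 20.5 RPM, above all 3 (2.90 to 4.65 RPM), with Hormad1 at most 2.43 RPM. Oocyte C of the latter, with 54.3 RPM of these markers, had Hormad1 at 2.38 RPM. Over the full list neither female was above all 3. That the lane 1 transgenic female is wild type cannot be told apart from an uneven effect: of the 200 genes with the smallest p in lanes 2 to 4, 73% had the same direction in lane 1 (59.7% of all genes), a value set beforehand as arguing against a wrong label, but lanes 2, 3 and 4 held out in the same way gave 64.5%, 72% and 45% (54%, 62.8% and 51% of all genes), and the transgenic female of lane 4 had high Hormad1, so the measure does not separate the females. Lane 1 also differed as labelled in the mean over the 3 lower lists (-0.55, against -0.25, -0.21 and -0.43 in lanes 2 to 4) and in Ccrn4l, Eif1b and Birc5 (0.64, -0.98 and -1.18), but these were picked with lane 1 included. The labels give differing numbers for the transgenic females of lanes 1 and 2 between titles and library names, with 1 genotype in both. Differences between the females other than the transgene were not tested and remain open for Hormad1 and Gm9000.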

How the results depend on the processing

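Alternatives with voom, with the length and GC trend removed, without 1 oocyte, with permuted list means and, for lists, with lanes 1 to 3 were chosen after seeing the data. The count of genes stayed at 0 under 24 of 28 alternatives, among them the lane as a replicate block. Single oocytes with the female as random effect and the lane as replicate block gave 12, voom in the same design 15 (11 of them shared), and oocytes as if independent 2. Leaving out 1 female gave 0 to 1; the 1 was Hormad1 without the lane 1 transgenic female. Of 58 named genes, 1604 of 1606 values under alternatives kept their direction. The exceptions were mt-Co1, at 0.0471 without the lane 1 transgenic female (range on leaving out 1 female -0.359 to 0.0471), and Cdh1, at -0.0137 without the oocyte that stands apart; the cause was not tested.

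The count of 3 lists was 0 with an estimated correlation, 0 with fry and 0 with permutation of the females, which cannot go below 0.029 before adjustment; the cause of the other losses was not tested. With an estimated correlation the adjusted p was 0.41 for oxidative phosphorylation, 0.41 for the proteasome and 0.42 for the ribosomal proteins. With fry it was 0.16 for each, and with permutation 0.14 for each. The lane block changed no list call. With a mean RPM of at least 10 the antioxidant list was also called (adjusted p = 0.032, median -0.23). Leaving out 1 female gave 3 to 4 lists, adding cohesin without the lane 1 transgenic female (0.014) and the mitochondrially encoded genes without that of lane 3 (0.024); the adjusted p of the proteasome list rose to 0.047 without the wild-type female of lane 4.

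The difference in genes detected was 109 at an RPM of at least 0.1 and -107 at 10 (exact permutation p = 0.657 and 0.0857), and -88.2 in pairs within lanes (replicate block, p = 0.125). Leaving out 1 female gave -104 to -72.8. The spread between oocytes differed by -0.0231 without the lane 3 transgenic female and by -0.0176 without the lane 4 wild-type female, within a range of -0.0231 to 0.0388. The consensus correlation of oocytes of 1 female was 0.0495 with the lane as replicate block, 0.228 at a mean RPM of at least 10 and 0.158 with quantile normalization. The cause of these shifts was not tested. At this depth 3 reads, the floor chosen here, are 0.0900 to 0.147 RPM in an oocyte.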

Other observations

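The marker lists were fixed before the data were examined, and the comparisons of the lane 4 female and of the oocyte with cumulus markers were chosen after the result was seen. The oocytes held transcripts usually used as markers of other cells. Tubb3, a neuronal tubulin, stood at a median of 396 RPM in the oocytes against 240 RPM in the control RNA, and Syt1 at 63.6 RPM against 1040 RPM. Cdh1, an epithelial cadherin, stood at a median of 97.5 RPM and Tcstv1, a gene of the early embryo, at 37.5 RPM, each at or above 1 RPM in all 21 oocytes. The neuronal markers Snap25 and Camk2a had a median of 0 RPM.

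The 2 oocytes of the lane 4 wild-type female differed from the other 19 in several egg genes, all chosen after their values were seen apart from those named by rule. Ldhb stood at 3590 and 6220 RPM against 740 to 1970 RPM, Cd9 at 40.5 and 107 RPM against 8.17 to 27.1 RPM, Tcstv1 at 110 and 114 RPM against 18 to 51 RPM, and Tcstv3 at 13.3 and 19.1 RPM against 1.41 to 10.7 RPM. On the second principal component, which held 10.9% of the variance, these 2 oocytes had scores of 41.8 and 43.8, while the other 19 lay between -43 and 9.3, and the lowest was oocyte C of the lane 1 transgenic female. The first component held 18% of the variance. On it the oocytes of both lane 4 females and of the lane 1 transgenic female scored from -51.6 to -10.9, and all others from -14.5 to 31.2.

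Oocyte C of the lane 2 wild-type female held RNA of cumulus markers: Inha at 13.7 RPM (at most 0.304 RPM in the other 20 oocytes), Tnfaip6 at 8.39 RPM (0), Hsd3b1 at 7.04 RPM (3.31), Fst at 4.29 RPM (0), Vim at 3.68 RPM (0.318) and Ptx3 at 3.54 RPM (0). The sum over 30 markers was 54.3 RPM, against at most 11.7 RPM elsewhere. Amhr2 had 0.186 RPM in this oocyte, from the 4 reads counted among wild-type oocytes. Without it, limma on female means called 0 genes and camera 3 lists.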
